A study of Mus musculus with 6 samples.

How the data were processed

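RNA sequencing libraries were made from left ventricle tissue of mice with myocardial infarction. Per the labels' protocols, total RNA was extracted, mRNA was separated and fragmented, and the libraries were sequenced on an Illumina NovaSeq. The authors deposited 1 table of raw read counts per library with 34745 genes each and no rows other than genes; 14527 genes had no count in any library. Per the submitters' processing notes the genome build was mm10 and the tools named are StringTie 1.3.0 and edgeR. The aligner, the program that counted the reads, the roles of the named tools and whether strand was used are not given in the sources used here, so reads of overlapping genes and antisense partners may have been assigned to either gene. Of the gene identifiers, 34344 matched the GENCODE M21 annotation of GRCm38 and 27776 had identical coordinates. Names that had been turned into spreadsheet dates (27 genes) were restored by identifier, and 122 genes share a name with another identifier. Among tested genes, 1626 overlap another listed gene on the same strand and 4692 on the opposite strand, by at least 1 base. Coordinates are those of the deposited files on mm10.

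Groups were taken from the sample titles, which call the libraries biological replicates and name no animal; p-values measure the spread between these libraries. NS is not spelled out in the labels, and the files of this group carry another abbreviation, SA, in their names. The files of replicate 3 of both groups are named in another style than those of replicates 1 and 2; whether they were made in another batch is not given in the sources used here. No pair of libraries agreed within sampling noise: chi-square per degree of freedom between counts was 10.0 to 25.7 within groups and 26.9 to 46.7 between them. The design, the 49 gene lists with 1010 names in all, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as added.

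Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group with its default minimum count of 10 and minimum total of 15, which left 13940 genes (12997 protein-coding), and scaled by TMM factors. Changes were tested with glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are MI-DAPA over MI-NS, and their standard errors are the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.139. CPM are counts scaled to TMM-adjusted library sizes, and log2 CPM used a prior count of 2. A floor of 3 counts per library corresponds to 0.146 to 0.174 CPM, for counting error only.

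Lists with at least 3 tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Of 49 lists, 30 were called (7 higher and 23 lower) with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.136 and 17 lists had an unadjusted p under 0.05; fry called 29. Members were counted past the threshold over all genes and adjusted over the list alone. Each library's list level was its mean log2 CPM. Levels of the groups did not overlap for 33 lists, against 10% by chance for each list. Some genes are in more than 1 list, such as Nppa in the fetal and stress and the atrial lists. All lists also use the same 6 libraries, so counts of lists are not counts of independent results. The smallest exact two-sided permutation p with 3 against 3 is 0.1. The lists cover heart muscle, matrix and fibroblasts, macrophages and other immune cells, vessels, further cell types a ventricle sample can hold, metabolism, mitochondria, ribosomes, stress responses, cell cycle, cell death, receptors and sex-linked genes.

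The named genes were the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups, leaving out gene models without an approved-looking symbol, a fixed set chosen for heart failure, macrophages and sodium-glucose transport, up to 4 members with the smallest p of each list described, and the sex-linked genes. Some genes that this rule covers are not reported here. Other members are named as examples or as members that did not pass, and were chosen after their values were seen.

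The steps were tested on simulated data with the real means and library sizes. Simulated genes were drawn independently of each other, while the estimated correlation between genes was 0.74 in the collagen and matrix list. The simulation therefore does not test camera's preset correlation of 0.01 on lists of correlated genes. Of 200 genes changed among 13940, edgeR recovered 34.3% at 1.5-fold, 79.1% at 2-fold and 93.9% at 4-fold; 13 of 151 calls (8.61%) were false, and camera called 10 of 10 changed and 0 of 40 unchanged lists.

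The alternatives were other scalings (RLE, upper quartile, library totals), other count filters, DESeq2 1.42.0, limma-voom with and without library weights, a robust fit, fold minimums, the replicate number as a block, leaving out each library, leaving out replicate 3 of both groups, and a surrogate variable (sva 3.50.0). Added after seeing the data were a correction for GC content and transcript length (mgcv 1.9.3), leaving out overlapping same-strand genes, leaving out mitochondrially encoded genes, leaving out replicate 1 or replicate 2 of both groups, and a batch term for replicate 3 against replicates 1 and 2.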

Results

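RNA was sequenced from left ventricle tissue of mice after myocardial infarction (MI), the death of heart muscle that follows a blocked coronary artery. The series holds 6 libraries in 2 groups of 3: MI-NS, used here as the control group, and MI-DAPA, mice given dapagliflozin, an inhibitor of the sodium-glucose cotransporter SGLT2 (gene Slc5a2). The labels number the libraries of each group as biological replicates. Each library listed counts for 34745 genes. Total counts were 20540321, 19766708 and 17207974 in MI-NS replicates 1 to 3. They were 20563188, 20161739 and 19086206 in MI-DAPA replicates 1 to 3. Genes of the mitochondrial chromosome took 38.0% ± 3.86 of the counts in MI-NS and 37.2% ± 3.07 in MI-DAPA (SD, n = 3, exact two-sided permutation p = 0.8; the smallest p that 3 against 3 allows is 0.1). The first principal component of the 500 most variable genes held 39.97% of their variance and had all MI-NS libraries on one side and all MI-DAPA libraries on the other. Spearman correlations across genes were 0.983 to 0.989 within groups and 0.973 to 0.980 between them.

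The comparison of MI-DAPA with MI-NS asks how dapagliflozin alters gene expression in the failing ventricle after infarction. Lists were tested by camera, a gene list test, with a preset correlation between genes. By this test, fetal and stress, extracellular matrix, fibroblast activation and complement genes were lower in MI-DAPA. Genes of calcium handling, fatty acid oxidation, the tricarboxylic acid (TCA) cycle and ketone use were higher. With an estimated correlation 0 of 49 lists passed (smallest adjusted p = 0.136), and 17 had an unadjusted p under 0.05. Of 13940 genes tested, 1212 were higher and 1092 lower in MI-DAPA by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p under 0.05). The falls were larger than the rises: 229 genes fell and 41 rose by at least 1 on the log2 scale, and the median change of the called genes was 1.37-fold upward and 1.55-fold downward. In 5154 tested genes (37.0%) the libraries of the groups did not overlap, against 10% by chance for 3 against 3. That 10% holds for each gene alone. Correlated genes separate together, so the share of 37.0% does not measure how far chance is exceeded. With library totals as the only scaling, 410 genes were higher and 1249 lower (24.7% of calls higher, against 52.6%), with the median of all genes shifted by -0.10 on the log2 scale. The 2304 calls became 1210 without MI-NS replicate 3, 998 without MI-DAPA replicate 1 and 1160 without MI-DAPA replicate 3. Fits with 2 libraries per group gave 24 calls without replicate 3 in both groups, whose files are named in another style. They gave 601 without replicate 1 and 1553 without replicate 2 in both groups. With 1 surrogate variable in the fit 7 genes were called, but that variable overlaps with the group (correlation 0.79).

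**Figure D1:**
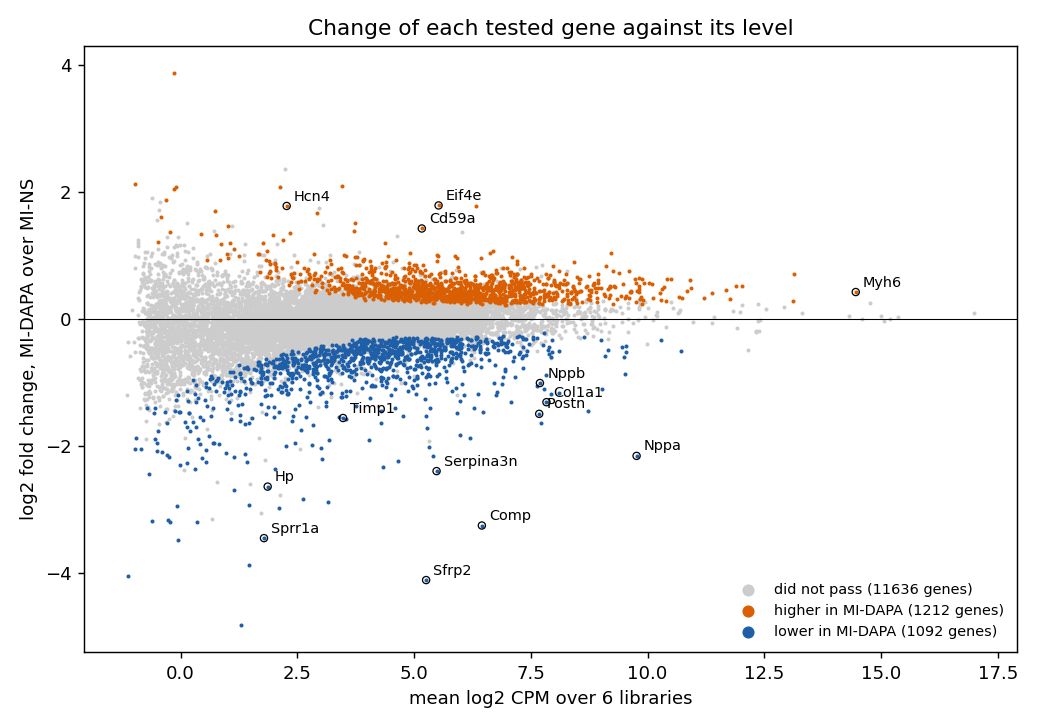
Each point is a tested gene, with its mean log2 CPM (counts scaled to library size) over the 6 libraries on the x axis and its log2 fold change, MI-DAPA over MI-NS, on the y axis. Orange and blue points are the 1212 higher and 1092 lower genes and grey points did not pass. Among the labelled genes the lower ones reach further from 0 than the higher ones, with Sfrp2 at -4.11 and Eif4e at 1.79. Clec3a, which is not labelled, lay at 3.87.

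Most genes of the fetal and stress list were lower in MI-DAPA. Bulk levels do not tell in which cells they fell, and members such as Acta2 and Timp1 are not particular to heart muscle cells. Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), fell 4.45-fold, from 1421 ± 112 CPM in MI-NS to 319 ± 44.6 CPM in MI-DAPA (SD, n = 3), a log2 change of -2.15 ± 0.12 (SE) with adjusted p = 0.000196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nppb, which encodes B-type natriuretic peptide (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), fell 2.01-fold, from 276 ± 19.3 to 138 ± 26.3 CPM (log2 change -1.01 ± 0.14, edgeR adjusted p = 0.0049). Among 18 fetal and stress genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), with a median log2 change of -0.55. The stress cytokine Gdf15 fell 3.95-fold (-1.98 ± 0.28), the tissue inhibitor of metalloproteinases Timp1 fell 2.94-fold (-1.56 ± 0.12), the smooth muscle actin Acta2 fell 1.76-fold (-0.82 ± 0.09) and Ankrd1, a stretch-responsive sarcomere gene, fell 1.41-fold (-0.50 ± 0.08). The adult myosin heavy chain Myh6 rose 1.34-fold (0.43 ± 0.09) and the fetal one, Myh7, fell 1.26-fold (-0.34 ± 0.09), with adjusted p of 0.0187 and 0.0369 by the edgeR test. The skeletal actin Acta1 had a log2 change of -0.40 ± 0.12 and did not pass (adjusted p = 0.0515, edgeR). By camera the list was lower with adjusted p = 8.10e-11, and had adjusted p = 0.136 with an estimated correlation. Myh7 kept its call only without MI-DAPA replicate 2, Myh6 lost its call without MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 3, and 7 list genes fell without MI-DAPA replicate 3. With any of the 6 libraries left out, 1 list gene rose.

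**Figure D2:**
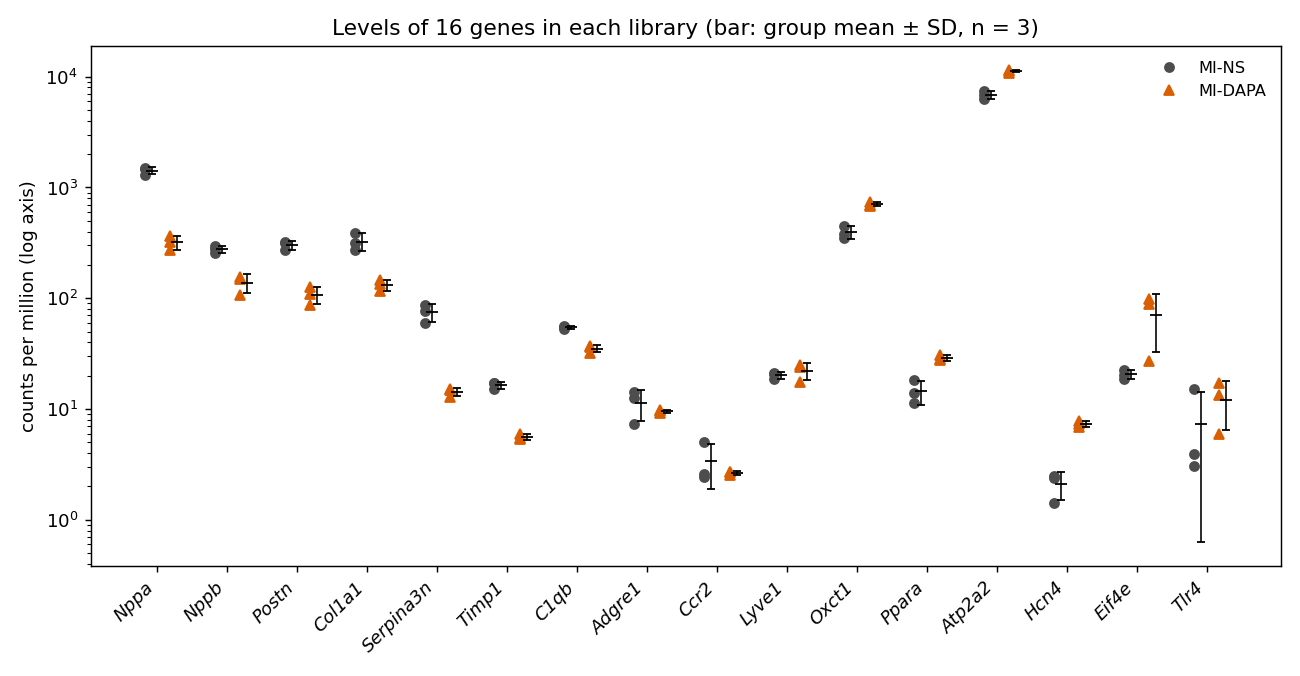
CPM of 16 genes in each library on a log axis, with circles for MI-NS, triangles for MI-DAPA and bars for the group mean ± SD (n = 3). Nppa lay around 1421 CPM in MI-NS and 319 CPM in MI-DAPA with no overlap, while the groups overlapped for Adgre1, Ccr2, Lyve1 and Tlr4.

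Most extracellular matrix genes fell. Of 35 collagen and matrix genes 33 fell and 0 rose (35 fell adjusted over the list alone), with a median log2 change of -1.16. Col1a1 fell 2.48-fold, from 325 ± 59.6 to 131 ± 15.1 CPM (log2 -1.31 ± 0.14). Col3a1 fell 2.74-fold, from 622 ± 134 to 227 ± 22.3 CPM (-1.45 ± 0.15), and the matricellular protein gene Postn fell 2.81-fold, from 302 ± 28 to 108 ± 19.5 CPM (-1.49 ± 0.13; SD of CPM and SE of log2, n = 3). The collagen crosslinking enzymes Lox and Loxl1 fell 5.0-fold (-2.32 ± 0.24) and 2.28-fold (-1.19 ± 0.09), Ltbp2, which binds to elastic fibres, fell 3.67-fold (-1.87 ± 0.18), and the matrix protein gene Cilp fell 2.22-fold (-1.15 ± 0.12). The adjusted p of these 7 genes ranged from 0.00121 for Loxl1 to 0.00262 for Col1a1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The members that did not pass were Lum (-0.49 ± 0.21) and Thbs2 (-0.54 ± 0.18). By camera the list was lower with adjusted p = 2.36e-45, and had adjusted p = 0.136 with an estimated correlation.

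Activated fibroblast genes and general fibroblast markers were lower in MI-DAPA. Of 17 activated fibroblast genes 15 fell and 0 rose (16 fell adjusted over the list alone), with a median of -1.41. Thbs4 fell 2.80-fold (-1.48 ± 0.14), the transcription factor Meox1 2.13-fold (-1.09 ± 0.15) and Wisp2 4.02-fold (-2.01 ± 0.28), while Fap, at -0.13 ± 0.17, did not pass. Of 18 fibroblast markers 11 fell and 0 rose (12 fell adjusted over the list alone), with a median of -0.54. Pi16 fell 1.88-fold (-0.91 ± 0.07), Mfap5 2.43-fold (-1.28 ± 0.18) and Col1a2 2.23-fold (-1.16 ± 0.16). The lineage markers Pdgfra (-0.22 ± 0.10) and Tcf21 (-0.78 ± 0.29) did not pass. Of 18 matrix proteases and inhibitors 9 fell and 0 rose (11 fell adjusted over the list alone), among them Mmp14 (-0.97 ± 0.14), Mmp3 (3.87-fold, -1.95 ± 0.28) and Adamts2 (1.99-fold, -1.0 ± 0.14). Of 18 TGF-beta targets 6 fell and 1 rose (7 and 1 adjusted over the list alone), including Tgfb3 (2.04-fold, -1.03 ± 0.12), Pmepa1 (1.57-fold, -0.65 ± 0.13) and Ctgf (1.84-fold, -0.88 ± 0.19). Tgfb1 itself had a log2 change of -0.50 ± 0.15 and did not pass (edgeR adjusted p = 0.0553). Camera gave adjusted p of 8.09e-29 for activated fibroblasts, 1.10e-12 for fibroblast markers and 1.05e-09 for proteases, and these 3 lists had adjusted p = 0.136 with an estimated correlation. The TGF-beta list had a camera adjusted p of 0.000189, and adjusted p = 0.342 with an estimated correlation. Ctgf lost its call without MI-NS replicate 3 or MI-DAPA replicate 3, and 3 TGF-beta targets fell without either of these libraries. The rise, of Ltbp1, kept its call only without MI-NS replicate 1.

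**Figure D3:**
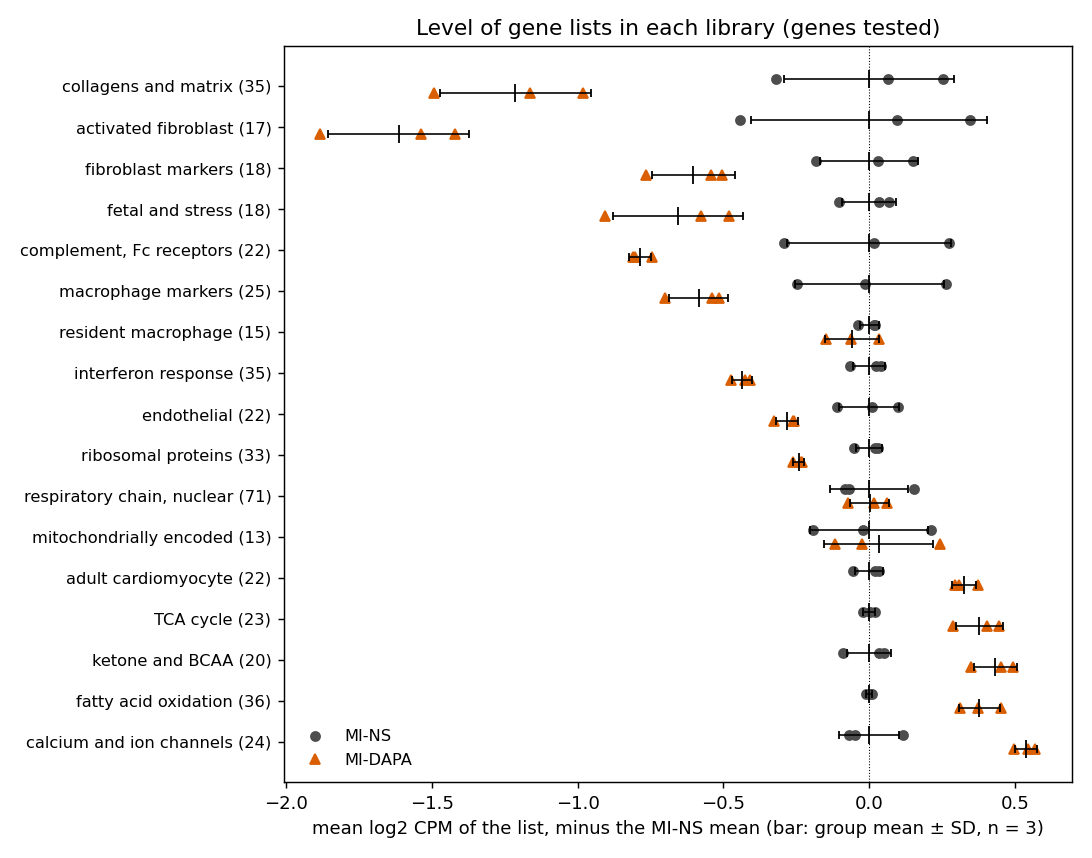
Mean log2 CPM of 17 gene lists in each library, relative to the MI-NS mean, with the number of tested genes in brackets and bars for the group mean ± SD (n = 3). The groups lay apart for 14 of them; they overlapped for the resident macrophage, nuclear respiratory chain and mitochondrially encoded lists.

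Calcium handling and ion channel genes rose. Of 24 such genes 21 rose and 0 fell (21 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.56. The pacemaker channel gene Hcn4 rose 3.44-fold, from 2.11 ± 0.593 to 7.34 ± 0.506 CPM (log2 1.78 ± 0.21), the sodium-calcium exchanger Slc8a1 2.06-fold (1.04 ± 0.15), the potassium channel subunit Kcnj11 1.71-fold (0.78 ± 0.11) and the sarcoplasmic reticulum calcium pump Atp2a2 1.64-fold (0.72 ± 0.09), with adjusted p from 0.00354 to 0.00551 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 22 adult cardiomyocyte genes 11 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.30, including Pln (1.43-fold, 0.52 ± 0.08), Ldb3 (1.35-fold, 0.43 ± 0.07) and Mybpc3 (1.38-fold, 0.46 ± 0.08). The troponins Tnnt2 (-0.01 ± 0.11) and Tnni3 (0.04 ± 0.10) and titin, Ttn (0.14 ± 0.27), did not pass. Camera gave adjusted p of 1.68e-16 and 4.08e-08 for the lists, and both had adjusted p = 0.136 with an estimated correlation. Without MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 3 the count of adult cardiomyocyte genes that rose was 6, 7 or 6.

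Genes of mitochondrial fuel use rose, while the respiratory chain lists were not called. The difference between these lists was not tested. After GC and length correction the nuclear respiratory chain list had a median of 0.062, against -0.042 before. Its camera adjusted p was then 0.0535. Of 36 fatty acid oxidation genes 26 rose and 2 fell (30 and 2 adjusted over the list alone), with a median of 0.42. The electron carrier Etfdh rose 1.48-fold (0.57 ± 0.07), the beta-oxidation enzyme Hadhb 1.62-fold (0.69 ± 0.09), the carnitine carrier Slc25a20 1.51-fold (0.59 ± 0.08), the pyruvate dehydrogenase kinase Pdk4 1.66-fold (0.73 ± 0.10) and the fatty acid sensor Ppara 1.99-fold (0.99 ± 0.16). The members that fell were Fabp4 (-0.43), an adipocyte and endothelial fatty acid binding protein, and Ucp2 (-0.38). Of 23 TCA cycle genes 15 rose and 0 fell (20 rose adjusted over the list alone), among them Dld (1.48-fold, 0.56 ± 0.06), Cs (1.46-fold, 0.55 ± 0.08) and Sdha (1.48-fold, 0.57 ± 0.08). Of 20 genes of ketone and branched-chain amino acid use 13 rose and 0 fell (14 rose adjusted over the list alone), including the ketone body enzyme Oxct1 (1.79-fold, 0.84 ± 0.10), the lactate and ketone transporter Slc16a1 (1.5-fold, 0.59 ± 0.06) and Ppm1k (1.65-fold, 0.72 ± 0.09). Camera gave adjusted p of 2.14e-15, 1.80e-13 and 1.96e-11 for these lists, and all 3 had adjusted p = 0.136 with an estimated correlation. Of 29 glycolysis and glucose genes 11 rose and 2 fell (13 and 2 adjusted over the list alone). Hexokinase Hk2 was up 1.5-fold (0.58 ± 0.07), glycogen synthase Gys1 up 1.61-fold (0.69 ± 0.09) and the lactate exporter Slc16a3 down 2.29-fold (-1.19 ± 0.19). The glycolysis list had a camera adjusted p of 4.20e-05, and adjusted p = 0.166 with an estimated correlation. Of 71 nuclear respiratory chain genes 6 rose and 1 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.643). Among 13 mitochondrially encoded genes 0 passed by edgeR (0 adjusted over the list alone; camera adjusted p = 0.703). Beside the calcium handling and fuel genes, markers of adult cardiomyocytes had a median of 0.30, and those of fibroblasts, macrophages and endothelium had medians of -0.54, -0.52 and -0.31. Without MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 3 the count of fatty acid oxidation genes that rose was 17, 16 or 15. Fabp4 lost its call without MI-DAPA replicate 3, Ucp2 kept its call only without MI-NS replicate 1, and the nuclear respiratory chain list had a camera adjusted p of 0.0129 without MI-NS replicate 2. Nuclear respiratory chain genes that rose numbered 3, 2, 2 and 3 without MI-NS replicates 1 and 3 and MI-DAPA replicates 1 and 3. Of that list 2 genes fell without MI-NS replicate 1, and 0 without any other library. Without MI-DAPA replicate 1 or 3, 1 glycolysis gene fell.

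Sodium and glucose transport genes include the drug's named target. Slc5a2, which encodes SGLT2 (ENSMUSG00000030781, chromosome 7, 128265657 to 128272430), had 0, 0 and 0 counts in MI-NS and 0, 1 and 4 counts in MI-DAPA. It was not tested, since it lay near the floor of 3 counts per library, and a difference was not detectable at this depth. Slc5a1, which encodes SGLT1, had 12, 5 and 7 counts in MI-NS and 11, 11 and 11 in MI-DAPA (log2 0.51 ± 0.41, edgeR adjusted p = 0.435). Of 12 sodium and glucose transport genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), including Slc8a1, the sodium pump subunit Atp1b1 (1.32-fold, 0.40 ± 0.07) and the glucose transporter Slc2a4 (1.32-fold, 0.40 ± 0.09). Camera adjusted p was 0.0309, and adjusted p = 0.339 with an estimated correlation; it was 0.109 without MI-NS replicate 2, 0.0551 without MI-NS replicate 3 and 0.069 with library totals as the only scaling. Slc2a4 lost its call, and 3 genes of the list rose, without MI-NS replicate 2, MI-DAPA replicate 1 or MI-DAPA replicate 3. No gene of the list fell by edgeR (0) without MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 3.

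Part of the macrophage markers fell. Of 25 macrophage markers 13 fell and 0 rose (15 fell adjusted over the list alone), with a median of -0.52. Lgals3, which encodes galectin-3, fell 4.07-fold (-2.03 ± 0.27), the complement genes C1qb and C1qa fell 1.55-fold (-0.63 ± 0.08) and 1.44-fold (-0.52 ± 0.10), and Fcer1g fell 1.79-fold (-0.84 ± 0.17). The identity markers Adgre1 (-0.25 ± 0.22), Cd68 (-0.25 ± 0.13), Csf1r (-0.27 ± 0.12) and Mrc1 (-0.31 ± 0.12) did not pass, with adjusted p from 0.106 to 0.471 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 13 monocyte-derived macrophage genes 8 fell and 0 rose (9 fell adjusted over the list alone). Haptoglobin, Hp, was down 6.22-fold (-2.64 ± 0.30), Ifitm3 down 1.64-fold (-0.72 ± 0.09) and Vcan down 1.65-fold (-0.73 ± 0.12). Bulk levels do not tell which cells these genes fell in, so fewer monocyte-derived macrophages are not shown. The monocyte receptor Ccr2 had a log2 change of -0.36 ± 0.29 (edgeR adjusted p = 0.437), which was 0.07 without MI-NS replicate 1. Of 15 resident macrophage genes 2 fell and 0 rose (0 adjusted over the list alone; camera adjusted p = 0.578), with Lyve1 at 0.14 ± 0.14. Both falls, of Igf1 and Gas6, kept their calls without MI-NS replicate 2, 0 did without MI-NS replicates 1 and 3 or MI-DAPA replicates 1 and 2, and without MI-DAPA replicate 3 only that of Igf1 did. Camera gave adjusted p of 9.24e-08 for macrophage markers, with adjusted p = 0.26 with an estimated correlation. For monocyte-derived genes it gave 2.03e-07, with adjusted p = 0.136 with an estimated correlation. The macrophage markers that fell numbered 8, 7, 4, 8 and 6 without MI-NS replicates 1 and 3 and MI-DAPA replicates 1, 2 and 3. The monocyte-derived genes numbered 5, 5, 5 and 4 without MI-NS replicates 1 and 3 and MI-DAPA replicates 1 and 3.

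Complement, interferon and cytokine genes were also lower. Of 22 complement and Fc receptor genes 13 fell and 0 rose (16 fell adjusted over the list alone), with a median of -0.58. C3 fell 3.11-fold (-1.64 ± 0.29), C4b 2.63-fold (-1.39 ± 0.23) and C1ra 1.97-fold (-0.98 ± 0.15). Of 35 interferon response genes 13 fell and 1 rose (17 and 1 adjusted over the list alone). Ifi27l2a was down 1.90-fold (-0.92 ± 0.09), Oas2 down 1.60-fold (-0.68 ± 0.10) and Stat2 down 1.53-fold (-0.62 ± 0.10). Camera gave adjusted p of 2.23e-10 and 1.75e-07 for these lists, and both had adjusted p = 0.136 with an estimated correlation. Of 19 cytokines and chemokines 6 fell and 0 rose (6 fell adjusted over the list alone), among them Cx3cl1 (1.75-fold, -0.80 ± 0.12), Cxcl10 (3.40-fold, -1.77 ± 0.40) and the monocyte attractant Ccl2 (2.27-fold, -1.18 ± 0.30, edgeR adjusted p = 0.029). The cytokine list had a camera adjusted p of 1.82e-05, and adjusted p = 0.246 with an estimated correlation. Il1b (-0.57 ± 0.46) and Nlrp3 (-1.0 ± 0.66) did not pass. Il6 with 10, 1 and 10 counts in MI-NS and 5, 4 and 3 in MI-DAPA and Tnf with 7, 12 and 5 against 5, 6 and 8 were below the filter. Of 31 NF-kB, inflammasome and Toll-like receptor genes 8 fell and 1 rose (13 and 1 adjusted over the list alone). Nfkbiz was down 1.75-fold (-0.81 ± 0.12), the pore-forming Gsdmd down 1.71-fold (-0.77 ± 0.12) and Txnip up 1.55-fold (0.63 ± 0.10). The NF-kB list had a camera adjusted p of 0.000189, and adjusted p = 0.249 with an estimated correlation. Nfkb1 (-0.25 ± 0.08), Tlr4 (0.75 ± 0.59) and Spp1 (-0.55 ± 0.39) did not pass. Of 10 MHC class II and dendritic cell genes 5 fell and 0 rose (8 fell adjusted over the list alone), including H2-Ab1 (1.56-fold, -0.64 ± 0.12). The MHC class II list had a camera adjusted p of 0.000326, and adjusted p = 0.136 with an estimated correlation. Without MI-NS replicates 1 and 3 and MI-DAPA replicates 1, 2 and 3, the cytokines that fell numbered 3, 1, 1, 2 and 4, and Ccl2 and Cxcl10 kept their calls only without MI-NS replicate 2. Without MI-NS replicates 1, 2 and 3 and MI-DAPA replicates 1 and 3, the NF-kB genes that fell numbered 2, 5, 3, 2 and 3. Without MI-NS replicates 1 and 3 and MI-DAPA replicates 1 and 3 the interferon genes numbered 7, 8, 8 and 6. The interferon gene that rose, Iigp1, kept its call only without MI-NS replicate 1 or MI-DAPA replicate 2, and 2 NF-kB genes rose without MI-NS replicate 3. Without MI-NS replicate 3 and MI-DAPA replicates 1 and 3 the MHC class II genes numbered 3, 1 and 2.

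Endothelial and ribosomal protein genes were lower as lists. Of 22 endothelial genes 8 fell and 0 rose (14 fell adjusted over the list alone), with a median of -0.31, including Egfl7 (1.40-fold, -0.48 ± 0.08), Sox18 (1.40-fold, -0.49 ± 0.10) and Pecam1 (1.25-fold, -0.32 ± 0.07). The endothelial list had a camera adjusted p of 1.72e-05, and adjusted p = 0.339 with an estimated correlation. Of 33 ribosomal protein genes 4 fell and 0 rose (9 fell adjusted over the list alone), with a median of -0.22 and Rpl3 down 1.34-fold (-0.42 ± 0.09). The ribosomal list had a camera adjusted p of 0.000244, and adjusted p = 0.136 with an estimated correlation. Without MI-NS replicates 2 and 3 and MI-DAPA replicates 1 and 3, 4, 3, 2 and 2 endothelial genes fell. Sox18 lost its call without MI-DAPA replicate 1 or 3, and Pecam1 without these or without MI-NS replicate 1 or 3. Without each of the 3 MI-NS libraries or MI-DAPA replicate 1, 1 ribosomal gene fell, without MI-DAPA replicate 2 it was 2 genes, and without MI-DAPA replicate 3 it was 0. Rpl3 lost its call without MI-DAPA replicate 1 or 3.

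Among the genes named for the size of their change, the falls were larger than the rises. The Wnt modulator Sfrp2 fell 17.3-fold, from 72.0 ± 57.2 to 4.17 ± 0.978 CPM (log2 -4.11 ± 0.70), the collagen-associated Cthrc1 14.6-fold (-3.87 ± 0.70) and Sprr1a, a small proline-rich protein, 10.9-fold (-3.45 ± 0.29). The cartilage oligomeric matrix protein Comp fell 9.52-fold, from 158 ± 85.6 to 16.6 ± 5.95 CPM (-3.25 ± 0.43). The immunoglobulin light chain constant region Igkc fell 7.64-fold (-2.93 ± 0.50), Col8a2 7.36-fold (-2.88 ± 0.42) and Col11a1 6.48-fold (-2.70 ± 0.70). The protease inhibitor Serpina3n fell 5.25-fold, from 74.9 ± 13.5 to 14.3 ± 1.27 CPM (-2.39 ± 0.14), and Cilp2 5.13-fold (-2.36 ± 0.40). Complement factor Cfb fell 7.89-fold (-2.98 ± 0.71); its model overlaps Gm20547 on the same strand, and the summed counts gave -1.93 ± 0.26. In MI-DAPA, Cthrc1 had 1, 7 and 11 counts and Cfb 49, 2 and 4, in part below the floor of 3 counts per library, which limits how well the size of these falls is known. The rises were smaller. The complement inhibitor Cd59a rose 2.69-fold, from 19.4 ± 0.69 to 52.2 ± 2.99 CPM (1.43 ± 0.08), and Aldh1l1, a folate enzyme, 3.17-fold (1.67 ± 0.21). Zfp568 rose 2.86-fold (1.52 ± 0.30), Btbd11 2.75-fold (1.46 ± 0.32), nebulin, Neb, 2.63-fold (1.39 ± 0.16) and Cubn 2.56-fold (1.36 ± 0.15). The Wnt inhibitor Wif1 rose 2.50-fold (1.32 ± 0.26) and the transcription factor Irx1 2.38-fold (1.25 ± 0.29). The translation factor Eif4e rose 3.46-fold (1.79 ± 0.40) with 22.6, 18.7 and 20.4 CPM in MI-NS and 98.5, 87.9 and 27.1 CPM in MI-DAPA. The adjusted p of these genes ranged from 0.000206 for Serpina3n and Cd59a to 0.0327 for Col11a1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without MI-NS replicate 1 the log2 change was -3.37 for Sfrp2, -3.27 for Cthrc1 and -1.83 for Col11a1, without MI-DAPA replicate 3 it was -4.57 for Cthrc1, and without MI-DAPA replicate 1 it was -5.49 for Cfb. Col11a1 kept its call only without MI-NS replicate 2 and Eif4e only without MI-NS replicate 1 or MI-DAPA replicate 3. Cfb lost its call without MI-NS replicate 1, MI-NS replicate 3 or MI-DAPA replicate 3. Irx1 lost it without MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 2, Btbd11 without MI-DAPA replicate 3 and Zfp568 without MI-DAPA replicate 1.

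Overlapping gene models gave 3 of the largest changes. Akap2, a protein kinase A anchoring protein (ENSMUSG00000038729, chromosome 4, 57717657 to 57896982), rose 3.45-fold (log2 1.79 ± 0.09, adjusted p = 0.000196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while Pakap, whose model on the same strand (57568179 to 57896984) contains nearly all of it, fell 3.53-fold (-1.82 ± 0.11). The summed counts of both changed by 0.18 ± 0.10 on the log2 scale, which did not pass. A second model named Tgfb1i1 (ENSMUSG00000108631, chromosome 7, 128248895 to 128253365) fell by 4.81 ± 0.41 on the log2 scale and lies within the main Tgfb1i1 model, which fell by 0.40 ± 0.10. The second model had 78, 89 and 98 counts in MI-NS and 3, 5 and 1 in MI-DAPA, near the floor of 3 counts per library, which limits how well the size of its fall is known; the summed counts changed by -0.61 ± 0.10. Pcdhgb1 of the gamma protocadherin cluster rose 4.22-fold (2.08 ± 0.53) and the summed counts of its overlapping models changed by -0.11 ± 0.08. Without MI-DAPA replicate 1 the Pcdhgb1 change was 1.36, and its call was lost without that library, MI-NS replicate 2, MI-NS replicate 3 or MI-DAPA replicate 3.

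**Figure D4:**
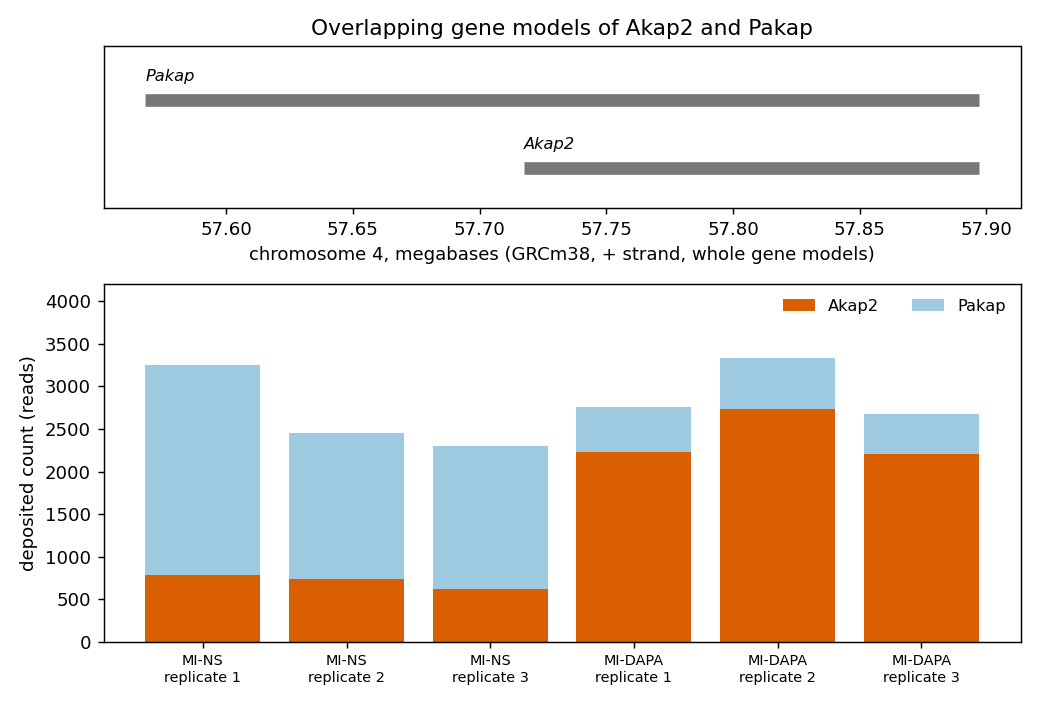
The upper panel draws the whole gene models of Akap2 and Pakap on chromosome 4 (GRCm38, megabases), and the lower panel stacks the deposited counts of each in every library from 0. Akap2 had 623 to 782 counts in MI-NS and 2200 to 2736 in MI-DAPA, and Pakap had 1677 to 2465 and 477 to 592.

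As a check on the samples, the Y-linked genes Ddx3y (0.14 ± 0.10), Eif2s3y (-0.03 ± 0.09) and Kdm5d (0.21 ± 0.14) were expressed in all 6 libraries and did not pass. Uty rose 1.40-fold (0.48 ± 0.10, adjusted p = 0.0177 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost without MI-NS replicate 3 or MI-DAPA replicate 1. Xist, the X-inactivation RNA, had 7, 6 and 3 counts in MI-NS and 1, 4 and 0 in MI-DAPA.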

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

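The alternatives added after seeing the data were the GC and length correction, leaving out overlapping or mitochondrially encoded genes, leaving out replicate 1 or 2 of both groups, and a batch term for replicate 3. The count of changed genes stayed within 1.5 times of 2304 under other scalings (RLE, upper quartile and library totals), other count filters, a robust fit, DESeq2, limma-voom, library weights, GC and length correction, and without overlapping or mitochondrially encoded genes, from 1659 to 2460. With library totals only, 410 genes were higher, against 1212; 1481 of the 1659 calls were shared. With a minimum log2 change of 1, 270 genes changed (41 higher, 229 lower), and with unadjusted p under 0.05 and that minimum, 396 changed (68 higher, 328 lower); both filters act on fold by construction. Leaving out 1 library gave 998 to 1863 genes (541 to 1087 higher, 457 to 844 lower). Without replicate 3 in both groups 24 genes changed (8 higher, 16 lower), without replicate 1 in both groups 601 (350 higher, 251 lower) and without replicate 2 in both groups 1553 (791 higher); these fits have 2 libraries per group. The files of replicate 3 are named in another style, so a batch may set it apart: within replicates 1 and 2 the count is 24, replicate 3 alone has 1 library per group and was not tested, and with a batch term for replicate 3 2072 genes changed (1992 shared) and 30 lists were called. The cause of the difference between these counts was not tested. With 1 surrogate variable 7 genes changed (2 higher, 5 lower); that variable was -0.31, -0.39 and -0.27 in MI-NS and 0.32, -0.11 and 0.75 in MI-DAPA, so it overlaps with the group. With a replicate block 2307 genes changed (2011 shared). Deviations of same-numbered libraries correlated by -0.005 to 0.113, which does not show that the numbers pair the libraries. The 0.113 belongs to the replicate 3 libraries, and differently numbered libraries of the groups reached at most 0.044. Mitochondrial genes took 42.0% and 40.7% of the counts in replicate 3 of MI-NS and MI-DAPA. In the other libraries they took 34.3% to 37.6%. A batch of replicate 3 stays open. The block lost the neutrophil (adjusted p = 0.0656) and atrial (adjusted p = 0.0802) lists of camera, leaving 28. Lists called numbered 0 with an estimated correlation, 27 with library totals (neutrophil, atrial and sodium and glucose transport lost), 29 with the filter of CPM of at least 1 in 3 libraries (neutrophil lost), 29 after GC and length correction (atrial lost), 29 with fry (26 shared, with TGF-beta, neutrophil, lysosome and atrial lost and Schwann cell, oxidative stress and sex-linked gained) and 26 to 32 without 1 library.

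Of 106 called named genes, 0 reversed in any alternative that tested them, and 4 kept their call in every one without a fold minimum. The groups do not overlap for 2298 of the 2304 called genes, so leaving out libraries could hardly reverse a called gene. The lack of reversals is therefore no separate support for the calls. Cd59a, Serpina3n and Nppa were called in all 24 alternatives without a fold minimum, and Akap2 in the 23 that tested it, which leaves out the fit without overlapping genes. Those that reversed had not passed: Ccr2 was 0.0709 without MI-NS replicate 1 (-0.544 without MI-NS replicate 2, the lowest value without 1 library) and 0.0452 without replicate 1 in both groups; Nlrp3 was 1.05 and Ddx3y -0.10 with the surrogate variable; Eif2s3y was 0.000903 with library weights, 0.0363 without MI-NS replicate 1, 0.0232 without MI-DAPA replicate 1 and 0.0772 without replicate 1 in both groups. The cause was not tested. Depth limits low genes such as Slc5a2, Il6 and Tnf.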

Other observations

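The tests of fibroblast number, of cells other than cardiomyocytes, of scar content, of cardiomyocyte number, of the share of cardiomyocyte RNA and of gp130 and STAT3 targets were chosen only after results they measure were seen, and the GC and length correction was added after seeing the data.

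Several cell types outside heart muscle were lower as lists. Of 16 pericyte and smooth muscle genes 5 fell and 1 rose (9 and 1 adjusted over the list alone), with the contractile gene Tagln down 1.89-fold (-0.92 ± 0.12) and the channel subunit Abcc9 up 1.5-fold (0.59 ± 0.09). This list had a camera adjusted p of 0.00182, and adjusted p = 0.136 with an estimated correlation. Of 6 epicardial and mesothelial genes 2 fell (2 adjusted over the list alone), the retinoic acid enzyme Aldh1a2 2.86-fold (-1.52 ± 0.19) and Krt18 3.88-fold (-1.96 ± 0.38); camera adjusted p was 0.00182, and adjusted p = 0.136 with an estimated correlation. Of 12 B and plasma cell genes 3 fell (3 adjusted over the list alone), Igkc, Igha (4.79-fold, -2.26 ± 0.47) and Jchain (4.21-fold, -2.07 ± 0.46). The B cell list had a camera adjusted p of 0.0182, with adjusted p = 0.249 with an estimated correlation, and 0.0653 without MI-NS replicate 1. In MI-DAPA Igha had 9, 9 and 2 counts and Jchain 3, 4 and 6, near the floor of 3 counts per library. Igha lost its call without MI-NS replicate 3, and Jchain without MI-NS replicate 1, MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 2. Of 21 angiogenesis genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Esm1 down 2.53-fold (-1.34 ± 0.25), Pdgfb down 1.43-fold (-0.52 ± 0.08) and Angpt1 up (0.85 ± 0.15). The angiogenesis list had a camera adjusted p of 0.0068, with adjusted p = 0.339 with an estimated correlation, and 0.0785 without MI-NS replicate 2. Of 29 lysosome and phagocytosis genes 7 fell and 2 rose (9 and 3 adjusted over the list alone), including the receptor Axl (1.44-fold, -0.52 ± 0.07) and cathepsin Ctsk (2.12-fold, -1.09 ± 0.18). The lysosome list had a camera adjusted p of 0.0148, with adjusted p = 0.65 with an estimated correlation, and 0.115 without MI-NS replicate 1. Alternative macrophage genes had 1 fall of 11, Il4ra (1.88-fold, -0.91 ± 0.10; 4 adjusted over the list alone; camera adjusted p = 0.0398, and adjusted p = 0.372 with an estimated correlation). Neutrophil genes had 1 fall of 8, Lcn2 (1.93-fold, -0.95 ± 0.17; 1 adjusted over the list alone; camera adjusted p = 0.0412, and adjusted p = 0.445 with an estimated correlation). The alternative macrophage list had adjusted p = 0.113 without MI-NS replicate 2 and 0.0735 without MI-NS replicate 3, and 2 and 3 of its genes fell without MI-NS replicate 1 and MI-DAPA replicate 2. The neutrophil list had 0.109, 0.0575 and 0.225 without MI-NS replicates 1 and 3 and MI-DAPA replicate 1, 0.069 with library totals as the only scaling and 0.128 with a filter of CPM of at least 1 in 3 libraries. Of 11 atrial genes 2 fell and 2 rose (3 and 2 adjusted over the list alone), with the transcription factor Tbx5 up 1.5-fold (0.59 ± 0.09). The falls include Nppa, which is also in the fetal and stress list. Clec3a rose from 4, 2 and 0 counts in MI-NS, near the floor of 3 counts per library, to 11, 50 and 28 counts in MI-DAPA. Mean log2 CPM of the atrial list was 3.87, 1.93 and 3.44 in MI-NS and 1.59, 3.56 and 3.18 in MI-DAPA, so MI-NS replicate 2 and MI-DAPA replicate 1 lay below the others. The atrial list had a camera adjusted p of 0.038, with adjusted p = 0.389 with an estimated correlation, 0.115 without MI-NS replicate 1, 0.225 without MI-DAPA replicate 1, 0.0783 with library totals as the only scaling and 0.069 after GC and length correction. Its median log2 change was -1.01 (-0.93 after that correction), and -0.24 without MI-NS replicate 1 and -0.41 without MI-DAPA replicate 1. Without MI-NS replicate 2, MI-NS replicate 3, MI-DAPA replicate 1 or MI-DAPA replicate 2, 2 angiogenesis genes fell, and without MI-NS replicate 1 or any MI-DAPA library 3 lysosome genes fell, with 4 without MI-NS replicate 3. Lysosome genes that rose numbered 1 without MI-NS replicate 1, MI-NS replicate 2 or MI-DAPA replicate 2, and 0 without the other libraries. Pericyte genes that fell numbered 3 and 2 without MI-DAPA replicates 1 and 3.

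The remaining lists were not called by camera, with some genes moving in both directions. Of 23 oxidative stress genes 5 fell and 4 rose (6 and 5 adjusted over the list alone, with camera adjusted p = 0.235). Nox4 was down 3.35-fold (-1.74 ± 0.27), Sod3 down 1.77-fold (-0.82 ± 0.10) and the mitochondrial peroxiredoxin Prdx3 up 1.33-fold (0.41 ± 0.06). Of 22 cell death and autophagy genes 5 fell and 3 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.671), with the survival gene Bcl2l1 up 1.75-fold (0.81 ± 0.13) and the autophagy kinase Ulk1 up 1.56-fold (0.65 ± 0.07). Of 17 renin-angiotensin and adrenergic genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.578), with the receptor Adra1a up 1.97-fold (0.98 ± 0.14). The median log2 change of this list was -0.13 and its mean 0.05, and the median was 0.045 without MI-NS replicate 2, -0.073 without MI-NS replicate 3 and -0.046 without MI-DAPA replicate 1. Of 21 unfolded protein response genes 4 rose and 1 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.331). Of 18 circadian genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.547). Of 17 hypoxia genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.858). Schwann cell genes had 2 falls of 10 (2 adjusted over the list alone; camera adjusted p = 0.113). Lymphatic genes had 1 rise and 1 fall of 8 (1 and 3 adjusted over the list alone; camera adjusted p = 0.605), with Pdpn down 2.24-fold (-1.17 ± 0.22). Adipocyte genes had 3 rises and 1 fall of 10 (3 and 3 adjusted over the list alone; camera adjusted p = 0.677), with Lpl up 1.44-fold (0.52 ± 0.08). Skeletal muscle and cartilage genes had 2 rises and 1 fall of 10 (2 and 4 adjusted over the list alone; camera adjusted p = 0.382) and immediate early genes 1 fall of 22 (0 adjusted over the list alone; camera adjusted p = 0.262). No gene passed by edgeR among 30 cell cycle, 12 erythrocyte and platelet, 5 T and NK cell or 3 mast cell genes (0 adjusted over the list alone in each; camera adjusted p of 0.643, 0.430, 0.789 and 0.734), and the 4 sex-linked genes had camera adjusted p = 0.238. Leaving out MI-NS replicate 2 gave camera adjusted p of 0.0448 for Schwann cell and 0.00208 for skeletal muscle and cartilage genes, and leaving out MI-DAPA replicate 2 gave 0.00258 for immediate early and 0.0318 for unfolded protein response genes. Most counts of these lists moved when 1 library was left out; those given next are without MI-NS replicates 1, 2 and 3 and MI-DAPA replicates 1, 2 and 3, in that order. Oxidative stress genes numbered 4, 4, 3, 3, 5 and 3 falls and 4, 4, 2, 2, 4 and 3 rises. Cell death genes had 2, 2, 1, 0, 5 and 0 falls. Renin-angiotensin and adrenergic genes had 4, 3, 3, 2, 3 and 3 rises and 1, 1, 0, 1, 1 and 0 falls. Unfolded protein response genes had 1, 1, 3, 0, 1 and 0 rises and 2, 1, 0, 0, 3 and 2 falls. Circadian genes had 2, 1, 1, 1, 2 and 1 rises and 2, 1, 0, 1, 2 and 1 falls, and hypoxia genes 1, 1, 1, 0, 1 and 2 rises and 1, 1, 1, 1, 2 and 0 falls. Schwann cell genes had 2, 3, 1, 0, 2 and 1 falls, lymphatic genes 0, 0, 1, 0, 1 and 0 rises and adipocyte genes 2, 1, 1, 1, 1 and 0 falls. Skeletal muscle and cartilage genes had 1, 1, 0, 0, 2 and 1 rises and 1, 4, 1, 1, 2 and 1 falls. Immediate early genes had 1, 0, 0, 0, 3 and 0 falls, with 1 rise without MI-DAPA replicate 1, and 1 erythrocyte and platelet gene rose without MI-DAPA replicate 2.

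Matrix and activated fibroblast genes fell by a median of -1.16 and -1.41, and cell makeup was weighed as an explanation. The 95% intervals of medians, here and below, came from resampling the genes of a list. They measure the spread between genes, which are correlated, and not the spread between libraries. Fibroblast markers outside both lists had a median of -0.46, which is 0.70 above the matrix median (95% interval 0.26 to 0.98). For these genes, fewer fibroblasts of every kind are argued against as the whole cause, with the spread between libraries untested. Endothelial markers lay 0.85 above the matrix median (0.46 to 1.05). For these genes, that argues against a smaller share of all cells other than cardiomyocytes as the whole cause. As a part of the cause this stays open, since endothelial markers were also lower (median -0.31). Adult cardiomyocyte markers had a median of 0.30 (0.17 to 0.40). For these genes, that argues against fewer cardiomyocytes as the cause of the falls of Nppa and Nppb. Of the 22 markers 11 rose and 0 fell, and Tnnt2, Tnni3 and Ttn did not pass. Their median is therefore an uncertain measure of the share of cardiomyocytes. The same 0.30 would arise with more scar tissue in the MI-NS pieces or with a smaller scar in the treated animals, and these cannot be told apart because no label gives the sampled region; an effect of the treatment on matrix genes stays open.

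Across genes, which are not independent replicates, log2 changes had a Spearman correlation of 0.13 with transcript length and -0.12 with GC content, over the 99.7% of tested genes that have a length. After correction for both, the calcium, fatty acid, TCA and ketone genes had a median of 0.44 (95% interval 0.40 to 0.50), which argues against length or GC bias as the cause of their rise. Ribosomal protein genes, which are short, had a corrected median of -0.15 (-0.18 to -0.12), against -0.22 before, so the trend accounts for part of that value but is argued against as the whole. The fatty acid, TCA and ketone genes had a median 0.12 above that of adult cardiomyocyte markers (95% interval -0.0099 to 0.26). Because the interval reaches 0, a larger share of cardiomyocyte RNA in the MI-DAPA pieces cannot be told apart from a rise of these genes themselves. The comparison takes the marker median as that share, although 11 of 22 markers did not pass, among them Tnnt2, Tnni3 and Ttn. Treatment stays among the open explanations for both groups of genes.

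For Akap2 and Pakap, a candidate explanation is a different division of reads between overlapping models, because the summed change was 0.18 (95% interval -0.005 to 0.37). A switch between transcripts of the locus, in which the total stays near level, would give the same counts and stays open. For the second Tgfb1i1 model the summed change was -0.61 (-0.81 to -0.41), against -4.81 for that model alone. That model held a small part of the summed MI-NS counts, so a much smaller summed change was given beforehand and decides nothing. A different division of reads alone would leave the total near level and raise the main model. The total fell, and the main model fell by 0.40. For these models, that argues against a different division as the whole cause, and as a part of the cause it stays open.

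The 6 libraries form 10 splits of 3 against 3, which are too few for a share under 0.05. Every split but the real one mixes the groups, so a difference between the groups adds to its spread and lowers its count. The counts of the mixed splits therefore do not measure what chance alone would give. The real split gave 2304 genes and the highest other split gave 3; 1 split gave as many as the real one, namely itself.

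Sprr1a, Serpina3n, Hp and Timp1 fell together, and a hypothesis is that genes downstream of the cytokine receptor subunit gp130 and the transcription factor STAT3 are lower. A list of 32 other such targets was written after these falls were seen, and 5 of its tested members are also in the lists fixed before, so their values were already in the results. Of 28 tested, 12 fell and 0 rose, with a median of -0.44 (95% interval -0.75 to -0.14), including Lbp (-0.92), Osmr (-0.89), Il1r1 (-1.01) and Socs3 (-0.73); the unadjusted camera p was 4.35e-06, and unadjusted p = 0.0117 with an estimated correlation. Without those 5 members, 9 of 23 fell and 0 rose, with a median of -0.34 (95% interval -0.73 to -0.048), an unadjusted camera p of 0.000331, and unadjusted p = 0.0171 with an estimated correlation. Among the 49 fixed lists 17 had an unadjusted p under 0.05 with an estimated correlation and 0 passed after adjustment, so this p does not set the targets apart from those lists. The hypothesis stays open: Stat3 (0.07), Il6st (0.06) and Lrg1 (0.04) did not pass, and many of the targets may also respond to other inflammatory signals, which was not tested.

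Tlr4 counts were 88, 63 and 256 in MI-NS and 119, 350 and 233 in MI-DAPA. The within-group SD of its log2 CPM was 1.03, rank 43 from the highest of 10592 genes with a mean log2 CPM of at least 2, where the median was 0.136.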
